A study of Mus musculus with 16 samples.

How the data were processed

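Total RNA of 16 mouse cell samples was measured by RNA sequencing, in 8 groups of 2 libraries. Per the labels' protocols, RNA was isolated with a miRNeasy micro kit, treated with DNase on the column and turned into libraries with a SMARTer stranded kit for total RNA. Embryonic stem cells (ESCs) were wild type, Actb knockout (KO) or without the Actb locus. Embryonic fibroblasts (MEFs) were wild type, Actg1 KO or without the Actg1 locus. Kidney fibroblasts (MKFs) were Kindlin-2 KO or carried the floxed gene, in which recombination sites flank the part to be removed. The labels number the libraries of a group 1 and 2 and do not say whether they came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

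The submitters' processing notes name FastQC, STAR 2.5.3a, featureCounts 1.6.0, Subread and DESeq2 1.14.1, and the genome build mm10 (GRCm38), with no role or order. Whether counting used the strand of the reads, and how reads matching several genes were treated, is not given. A table of gene values per cell type was deposited. The deposited values are a score in whole numbers that reads as gene read counts divided by 1 factor per library and rounded. This reading comes from the values: low values leave regular gaps in libraries where 1 read is worth more than 1, and the median ratio between libraries of a table is near 1. From those gaps and ratios, 1 read was estimated to be worth between 0.715 and 1.30 in the libraries. Because of the rounding, the values were not treated as counts, and they are called normalised read counts here. Each table was normalised on its own, so tests between groups were run only within a table, and levels from different tables are not on 1 scale. The checks on feeder cells and on Actg1 reads alone set tables side by side, by values per 1000000 of a library's sum or by ratios within a table, and they are approximate for that reason. Every gene in the ESC and MEF tables reaches at least 4 in some library and every gene in the MKF table at least 5, so genes below those levels were not analysed here.

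The tables hold 23083 (ESC), 21615 (MEF) and 18288 (MKF) genes, of which 23045, 21573 and 18257 were found by Ensembl identifier in the mouse annotation on GRCm38 (GENCODE M21) used for symbols, positions and transcript classes. The summed values per library were 16022043 to 16529089 (ESC), 20305511 to 22094490 (MEF) and 15565648 to 16324223 (MKF). The estimated numbers of reads counted on genes were 12720000 to 22820000, 19250000 to 24470000 and 14980000 to 17160000. These read numbers are approximate. The mitochondrial ribosomal RNAs took 10.7 to 17.0 percent of the summed values, and protein-coding genes 75.0 to 83.1 percent. Within each group, the 2 libraries differed by more than sampling noise (median chi-square per gene between 1.59 and 6.79), and their log2 values correlated across genes with a mean of at least 50 at 0.981 to 0.996, so no library was counted as a repeat of another. Libraries of the same number deviated together in ESCs, with correlations of their deviations across genes of 0.678, 0.349 and 0.492 between the 3 groups. The pairing of ESC libraries comes from these values, as the labels give only the numbers. The tests stay without a block, and the value with a replicate block stands beside an ESC result where it changes a call or moves a count of calls by over 1.5 times.

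Tests used limma 3.58.1 in R 4.3.3 on log2(value + 1), with a group-means model, all groups of a table in 1 fit, empirical Bayes moderation with a trend in the mean, and genes with a mean value of at least 1. The test is two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison. A gene is said to have risen, fallen or changed only at an adjusted p below 0.05. The residual degrees of freedom were 3 (ESC and MEF) and 2 (MKF), with prior degrees of freedom of 5.4, 4.57 and 2.82. A quasi-likelihood test on counts had been planned, with this limma test named for values that are not counts. Fold changes are on the log2(value + 1) scale, which understates changes of genes with low values. Means are given with SD and n = 2. Where both libraries of a group are at 0, the fold is a lower bound, computed with the value of 3 reads per library in place of 0. Where a group's mean lies between 0 and about 3, the levels of both groups are given in place of a fold, with or without the difference on the log2(value + 1) scale. Bounds cover counting error only, and reads without molecular identifiers are not independent molecules. The test was run on simulated data first, with 1 noise level per comparison. False calls were 1 among 22948 genes (ESC KO against wild type), 2 among 21475 (MEF KO against wild type) and 0 among 18267 (MKF KO against floxed). Of 50 genes changed by 2-fold 86, 100 and 84 percent were called, and of 50 changed by 1.5-fold 40, 72 and 50 percent.

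The 35 gene lists were written by hand from textbook knowledge: families, cytoskeletal and adhesion genes, signalling and stress targets, cell cycle phases, and markers of other cell types. Each list with at least 5 tested members was tested in each comparison with limma's camera, two-sided, with a preset correlation between genes of 0.01, adjusted over all 241 tests. The same test with an estimated correlation stands beside it. Each list is given with its numbers of members that rose or fell over all genes tested and adjusted over the list alone. The actin list holds Actb and Actg1, and the kindlin and talin list holds Fermt2. A mutated gene was not left out of its family's list. With the preset correlation 74 of 241 tests passed, 48 upward and 26 downward. With an estimated correlation 0 of 241 passed (smallest adjusted p = 0.364, 26 at an unadjusted p below 0.05), so no list result holds under it. limma's fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes, passed 125. In none of the 74 did the median and the test differ in sign.

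Genes similar in sequence to a mutated mRNA were found by matching every annotated transcript of Actb, Actg1 and Fermt2 against all annotated transcripts with blastn 2.17.0 (word size 11, E at most 1e-05, same strand), leaving out the mutated gene. Overlaps between comparisons that share control libraries were set beside 20 simulations of unchanged groups and beside the overlap of independent lists of the same sizes. Medians of log2 fold changes per chromosome used genes with a mean value of at least 50 and chromosomes with at least 100 such genes. A shift of at least 0.3 was counted, and windows were tested on autosomes, in windows of 20 Mb with at least 10 genes.

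The planned test, the gene lists and the rule for naming genes were fixed before the data were examined. By that rule, the genes named are the mutated gene and the tested members of its family. Of the genes that changed, with a mean of at least 5 per 1000000 in the higher group and libraries that do not overlap, the 8 that rose most and the 8 that fell most are considered (4 and 4 for KO against locus deletion), leaving out symbols without a described gene. Of each list discussed, up to 4 members with the smallest adjusted p are named. Any other gene is said to have been chosen after its values were seen. Some genes that the rule covers are not reported here. The alternatives tried were other thresholds, 4 other scalings, other filters and pseudocounts, precision weights, fits with only the 4 libraries of a comparison, a replicate block, chromosome medians set to 0 and leaving out each library in turn.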

Results

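The data set comprised 16 RNA sequencing libraries from mouse cells in which 1 gene had been disrupted, in 8 groups of 2. In transcriptional adaptation, a mutant gene is said to alter the expression of genes related to it, and the series asked about this for 3 genes. Actb, the gene of beta-actin, was studied in embryonic stem cells (ESCs) with a knockout (KO) and with a deletion of the whole locus, which is meant to leave no mutant transcript to be made. Actg1, the gene of gamma-actin, was studied in the same way in embryonic fibroblasts (MEFs). Kindlin-2, an activator of integrins encoded by Fermt2, was studied in kidney fibroblasts (MKFs) with a KO and with cells carrying the floxed gene. All levels below are normalised read counts as means ± SD of 2 libraries, and every adjusted p for a gene is from limma across all genes tested.

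The actin genes considered lie on GRCm38 at chromosome 5, 142903115 to 142906754 (Actb, ENSMUSG00000029580), chromosome 11, 120345690 to 120348542 (Actg1, ENSMUSG00000062825), chromosome 19, 34241090 to 34255590 (Acta2, ENSMUSG00000035783), chromosome 8, 123891769 to 123894751 (Acta1, ENSMUSG00000031972), chromosome 2, 114047282 to 114053548 (Actc1, ENSMUSG00000068614) and chromosome 6, 83512905 to 83536265 (Actg2, ENSMUSG00000059430). Fermt1 (ENSMUSG00000027356) lies on chromosome 2 at 132904389 to 132945906, Fermt2 (ENSMUSG00000037712) on chromosome 14 at 45458795 to 45530118 and Fermt3 (ENSMUSG00000024965) on chromosome 19 at 6998958 to 7019469. All are on the minus strand. Actin genes and their processed pseudogenes are nearly identical in coding sequence, so the split of reads among them is uncertain.

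In Actb KO ESCs, Actb mRNA was lowered but most of it remained, and the genes of 3 other actins rose: Actg1, the other cytoplasmic actin, Acta2, the smooth muscle alpha-actin, and Acta1, the skeletal muscle alpha-actin. Many targets of the serum response factor (SRF), which responds to free actin monomer through its MRTF partners, rose with them, led by Myl9, a myosin light chain. Some targets of WNT signalling, Myc among them, also rose. Some genes of glycolysis and of the response to low oxygen fell, among them Bnip3, and so did some genes of the integrated stress response, among them Stc2. H19 and Dio3, both imprinted, were among the genes that rose most.

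Actb stood at 23178.5 ± 667 (SD, n = 2) in KO and 35252 ± 1573 (SD, n = 2) in wild-type ESCs, a log2 fold change of −0.60 (SE 0.0933, adjusted p = 0.0112), with both KO libraries below both wild-type libraries. Actg1 stood at 10048.5 ± 756 against 5100 ± 503, a rise of 0.98 (SE 0.122, adjusted p = 0.00481). Acta2 rose from 5.5 ± 4.95 to 1598 ± 46.7, by 8.19 on the log2 scale (SE 0.46, adjusted p = 0.000111). Acta1 rose from 4 ± 2.83 to 29.5 ± 2.12 (log2 fold change 2.73, adjusted p = 0.0411). Actc1, the cardiac actin, was at 21 ± 2.83 against 3.5 ± 3.54 (2.55, adjusted p = 0.0625) and Actg2, the enteric smooth muscle actin, at 13 ± 4.24 against 1 ± 1.41 (2.98, adjusted p = 0.099), and neither passed the test. With a replicate block both passed (adjusted p = 0.0284 and 0.024). As a list, the 6 actin genes had 3 that rose and 1 that fell, with 5 and 1 adjusted over the list alone (camera, adjusted p = 0.00102; adjusted p = 0.543 with an estimated correlation). These calls rest on the spread shared by all groups: with any 1 library of the comparison left out, Actg1 kept a log2 fold change of 0.88 to 1.08 but had an adjusted p of 0.123 to 0.176, and Actb had an adjusted p of 0.123 to 0.207. Acta1 also lost its call with each library left out (adjusted p = 0.145 to 0.33) and Acta2 with either KO library left out (highest adjusted p = 0.114). Acta1 further lost it with a pseudocount of 0.5 (adjusted p = 0.055), a setting chosen after the data were seen, and Acta1 and Actb lost it in fits of only the 4 libraries compared (adjusted p = 0.0843 and 0.0581). Actc1 passed with a pseudocount of 5 (adjusted p = 0.0363). No scaling turned the direction of an actin gene.

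**Figure D1:**
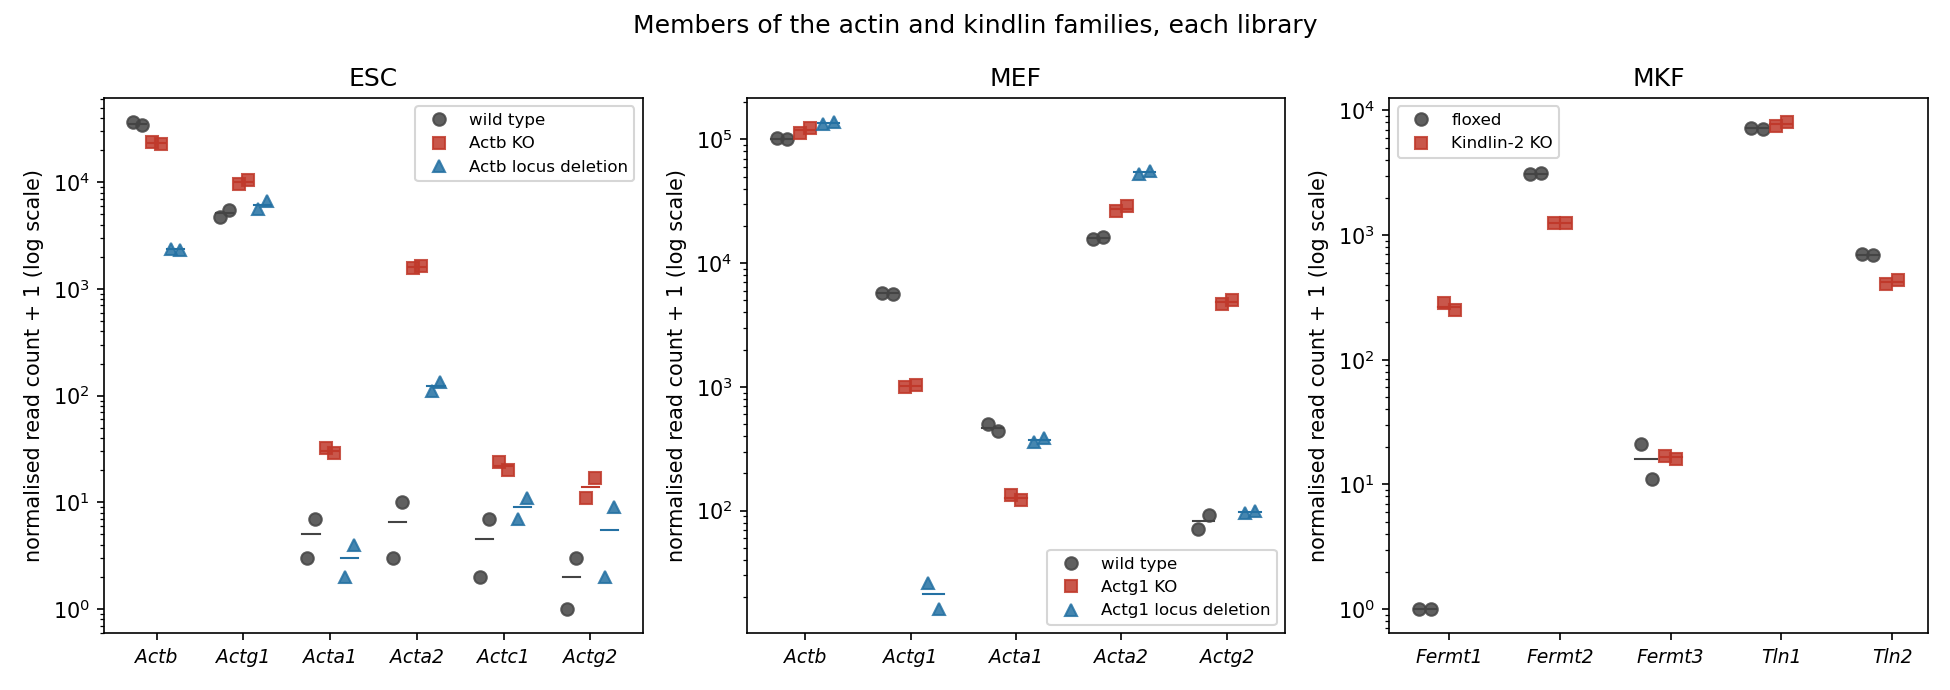
Normalised read count plus 1 (log axis) of the actin genes in the ESC and MEF libraries and of the kindlin and talin genes in the MKF libraries; each point is a library and each bar a group mean (n = 2). Acta2 is highest among the ESC groups in KO (mean 1598), Actg2 among the MEF groups in KO (mean 4854.5), and Fermt1 is at 0 in both floxed MKF libraries.

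The SRF and MRTF targets held 17 genes that rose and 0 that fell of 33 tested, with 20 and 1 adjusted over the list alone (camera, adjusted p = 1.2e-15; adjusted p = 0.364 with an estimated correlation). Myl9 rose from 25.5 ± 0.707 to 835 ± 38.2, Cnn2, a calponin, from 290 ± 1.41 to 1523.5 ± 95.5, Flna, a filamin that crosslinks actin filaments, from 5112.5 ± 98.3 to 20231.5 ± 514, and Tpm1, a tropomyosin, from 1350.5 ± 120 to 4481.5 ± 148. Among regulators of actin monomers and filaments, 9 of 31 rose and 0 fell, with 11 and 2 adjusted over the list alone (camera, adjusted p = 0.000152; adjusted p = 0.364 with an estimated correlation). They included the filament-severing factor Dstn (log2 fold change 1.56), Wdr1 (1.23), the monomer-binding Tmsb4x (1.02) and Pfn1 (0.79). Of the integrin adhesion list 6 of 34 rose and 1 fell, with 8 and 4 adjusted over the list alone (camera, adjusted p = 0.0181; adjusted p = 0.643 with an estimated correlation). Lpp, Itga1 and Actn4 rose among them. Fermt2 (0.96), Fermt3 (1.12) and Tln1 (0.66) rose among the 5 kindlin and talin genes (3 and 1 adjusted over the list alone; camera, adjusted p = 0.00403; adjusted p = 0.41 with an estimated correlation). These 3 calls were lost with each library left out (adjusted p = 0.0925 to 0.228).

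Of the glycolysis and low-oxygen list 12 of 29 fell and 0 rose, with 17 and 0 adjusted over the list alone (camera, adjusted p = 4.54e-12; adjusted p = 0.382 with an estimated correlation). Bnip3, a mitophagy receptor, fell from 331 ± 24.0 to 66.5 ± 2.12, the lactate exporter Slc16a3 from 317.5 ± 10.6 to 92 ± 5.66, and Ndrg1 and Vegfa fell by 1.65 and 1.36 on the log2 scale. Of the integrated stress response list 9 of 25 fell and 0 rose, with 15 and 1 adjusted over the list alone (camera, adjusted p = 2.02e-10; adjusted p = 0.364 with an estimated correlation). These included Stc2, Vldlr, Gpt2 and Nupr1. Cholesterol synthesis genes fell in 6 of 21 cases and rose in 0, with 9 and 0 adjusted over the list alone (camera, adjusted p = 6.12e-06; adjusted p = 0.509 with an estimated correlation). WNT targets rose in 6 of 15 cases and fell in 0, with 7 and 0 adjusted over the list alone (camera, adjusted p = 4.23e-06; adjusted p = 0.364 with an estimated correlation): Myc rose from 19 ± 4.24 to 209.5 ± 36.1, Sp5 from 21.5 ± 0.707 to 89 ± 2.83, Lef1 from 20 ± 1.41 to 87 ± 17.0, and Axin2 from 417 ± 56.6 to 956 ± 136. Mesoderm and primitive streak genes rose in 5 of 19 cases (8 rose and 2 fell adjusted over the list alone; camera, adjusted p = 0.000694; adjusted p = 0.522 with an estimated correlation), among them Bmp4 (log2 fold change 2.66), T (1.94) and Cdx1. Of the naive and core pluripotency list 6 of 27 rose and 2 fell, with 10 and 4 under a replicate block and 14 and 3 adjusted over the list alone (camera, adjusted p = 0.000353; adjusted p = 0.382 with an estimated correlation). Utf1, Lin28a and Nr0b1 were among those that rose. Of macrophage and blood cell markers 2 of 5 rose, Laptm5 (0.92) and Cd68 (1.19), and 0 fell. Of neural crest and neuronal markers 3 of 10 rose, Nefm (2.68), Nefl (1.47) and Tfap2a (0.88), and 0 fell. The 7 mitochondrially encoded genes had a median of 0.55 and 0 calls, or 3 that rose under a replicate block. These 3 lists were called (camera, adjusted p = 0.0181, 0.0358 and 0.0201). With an estimated correlation they had an adjusted p of 0.659, 0.543 and 0.659. The 35 tested factors of nonsense-mediated and general mRNA decay had 0 calls in limma (1 fell under a replicate block), also 0 adjusted over the list alone, and the list was not called (camera, adjusted p = 0.491; adjusted p = 0.882 with an estimated correlation; fry adjusted p = 0.574).

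In all, 1126 of 23054 genes changed in limma, 563 higher and 563 lower, and 255 and 260 of them by at least 2-fold. With a replicate block 921 were higher and 929 lower. Scaled without the genes that take over 1 percent of a library, 470 were higher and 785 lower. Further genes that rose most were Rhox6 (158 ± 42.4 against 6 ± 1.41), Spry4, an inhibitor of receptor tyrosine kinase signalling (424.5 ± 13.4 against 20.5 ± 2.12), Enox1 (562 ± 9.90 against 40.5 ± 10.6), H19 (2458 ± 307 against 178.5 ± 30.4), Dio3, which inactivates thyroid hormone (470.5 ± 3.54 against 38 ± 4.24), and Anxa3 (112.5 ± 21.9 against 8.5 ± 0.707), with adjusted p from 2.68e-05 to 0.00133. Those that fell most were the transcription factor Bhlhe40 (28.5 ± 7.78 against 385.5 ± 6.36), Slfn9 (49 ± 5.66 against 658.5 ± 87.0), Copz2 (7 ± 1.41 against 100 ± 21.2), Igfbp4 (20 ± 5.66 against 185 ± 1.41), Sgo2b (70 ± 1.41 against 513 ± 97.6), Otx2, a factor of the later epiblast (17.5 ± 0.707 against 101.5 ± 14.8), Stc2 and A2m, with adjusted p from 7.64e-05 to 0.00117. Rhox6, Slfn9 and Sgo2b have close copies in the genome and share the uncertainty of read assignment. On chromosome 8 the median log2 fold change of 615 genes was −0.35, against −0.001 to 0.08 on the other 18 autosomes. The number of calls depended on having both libraries of each group: without KO library 1 it was 0 (limma; 2898 at an unadjusted p below 0.05), without KO library 2 it was 18, and without either wild-type library 4, where the lone library is assumed to vary like the other groups. Of the 62 genes that passed and that the naming rule covers, 0, 11, 4 and 4 still passed in these fits.

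In ESCs without the Actb locus, Actb mRNA fell to a small remainder. Actg1 did not pass the test, while Acta2 rose, though to a lower level than in the KO. Many SRF targets rose here as well, with Myl9 and Flna among the leaders, as did Lcp1, an actin-bundling protein. Most genes of cholesterol synthesis and many of glycolysis and the stress response fell, and H19 fell where it had risen in the KO. Evc and Evc2, neighbouring genes of hedgehog signalling in cilia, fell together.

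Actb stood at 2354 ± 25.5 (SD, n = 2) in locus deletion ESCs, 6.68 percent of the wild-type level (log2 fold change −3.90, adjusted p = 1.1e-06). Actg1 was at 6118.5 ± 704 against 5100 ± 503 (0.26, SE 0.122, adjusted p = 0.218), with both locus deletion libraries above both wild-type libraries, so a small rise is not excluded. Acta2 rose to 121.5 ± 17.7 (4.48, adjusted p = 0.00112), a call lost with either locus deletion library left out (highest adjusted p = 0.0617). Acta1 was at 2 ± 1.41 against 4 ± 2.83 (−0.70, adjusted p = 0.525), Actc1 at 8 ± 2.83 against 3.5 ± 3.54 (1.23, adjusted p = 0.264) and Actg2 at 4.5 ± 4.95 against 1 ± 1.41 (1.29, adjusted p = 0.404). The actin list had 1 gene that rose and 1 that fell, also adjusted over the list alone, and was not called (camera, adjusted p = 0.807; adjusted p = 0.94 with an estimated correlation).

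Of the SRF and MRTF targets 19 of 33 rose and 2 fell, with 21 and 2 adjusted over the list alone (camera, adjusted p = 4.57e-13; adjusted p = 0.364 with an estimated correlation). Myl9 rose to 487 ± 76.4, Cnn2 to 2047 ± 267, Flna to 26598.5 ± 2420 and Dstn to 13201.5 ± 279. Of the actin regulators 12 of 31 rose and 0 fell (13 and 1 adjusted over the list alone; camera, adjusted p = 5.49e-05; adjusted p = 0.364 with an estimated correlation), including Wdr1 (log2 fold change 1.73), Tmsb4x (1.32) and Cap1 (1.17). As in the KO, Fermt2 (0.79), Fermt3 (2.23) and Tln1 (0.76) rose, each a call lost with some library left out (highest adjusted p = 0.0684). Of the integrin adhesion list 12 of 34 rose and 3 fell, and of the pluripotency list 7 of 27 rose and 3 fell (11 and 3 under a replicate block). The kindlin and talin, integrin and pluripotency lists were called (camera, adjusted p = 0.00251, 0.00374 and 0.000238). With an estimated correlation they had an adjusted p of 0.395, 0.547 and 0.382. WNT targets rose in 6 of 15 cases here too and fell in 0, though the list was not called (camera, adjusted p = 0.107). Cholesterol synthesis genes fell in 18 of 21 cases and rose in 0 (20 and 0 adjusted over the list alone; camera, adjusted p = 3.09e-15; adjusted p = 0.364 with an estimated correlation). They included Msmo1 (1071 ± 105 against 3849.5 ± 446), Cyp51 (857 ± 17.0 against 1871.5 ± 149) and Dhcr7 (129.5 ± 29.0 against 497 ± 63.6). Glycolysis and low-oxygen genes fell in 18 of 29 cases and rose in 0 (23 and 1 adjusted over the list alone; camera, adjusted p = 4.01e-14; adjusted p = 0.364 with an estimated correlation), with lactate dehydrogenase Ldha at 2408.5 ± 289 against 7374.5 ± 791. Of the integrated stress response list 12 of 25 fell and 0 rose (14 and 1 adjusted over the list alone; camera, adjusted p = 5.86e-07; adjusted p = 0.364 with an estimated correlation). S phase genes fell in 7 of 24 cases and rose in 0 (12 and 0 under a replicate block and also adjusted over the list alone; camera, adjusted p = 0.000435; adjusted p = 0.398 with an estimated correlation). Cdt1, Rrm1, Rrm2 and Ccne2 fell among them. Of 23 replication-dependent histones 1 fell and 0 rose, or 5 and 0 under a replicate block (camera, adjusted p = 0.0156; adjusted p = 0.882 with an estimated correlation). The list of COMPASS and histone H3K4 methylation genes had 7 genes that rose of 17 and 0 that fell (8 and 0 adjusted over the list alone; camera, adjusted p = 0.00251; adjusted p = 0.509 with an estimated correlation), with Setd1b at 1247 ± 163 against 654 ± 67.9 and smaller rises of Kmt2a (log2 fold change 0.55), Kmt2c (0.54) and Kmt2d (0.47). In KO ESCs the same list had 1 gene that rose, Setd1b (1279.5 ± 70.0), 0 that fell, and 4 that rose adjusted over the list alone. With a replicate block 3 rose, as Kmt2c (log2 fold change 0.37, adjusted p = 0.0324) and Kmt2a (0.34, adjusted p = 0.0433) then passed (for the list, camera, adjusted p = 0.0102; adjusted p = 0.522 with an estimated correlation).

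Of 23054 genes, 1196 were higher and 1384 lower, and 443 and 725 of them by at least 2-fold. Rhox6 (759 ± 173) and Rhox9 (208 ± 66.5 against 2.5 ± 0.707), homeobox genes of the X chromosome with close copies, rose most, followed by Lcp1 (1177.5 ± 58.7 against 29 ± 0), Dio3 (873.5 ± 153), Itga1, an integrin subunit for collagen (113.5 ± 12.02 against 4.5 ± 0.707), and Tgm3 (90 ± 1.41 against 7.5 ± 6.36). Besides Actb, those that fell most were Slfn9 (33.5 ± 4.95), Evc (7 ± 0 against 141.5 ± 16.3), Bhlhe40 (24.5 ± 3.54), Evc2 (15 ± 2.83 against 239.5 ± 33.2), Aire (6.5 ± 4.95 against 94.5 ± 30.4), Lefty1, an inhibitor of Nodal signalling (8 ± 7.07 against 103.5 ± 6.36), and H19 (16 ± 9.90), with adjusted p of at most 0.00331. On chromosome 8 the median log2 fold change was −0.40, against −0.05 to 0.10 on the other 18 autosomes. Left out one at a time, locus deletion libraries 1 and 2 gave 331 and 370 calls, and wild-type libraries 1 and 2 gave 58 and 76. Of the 53 genes that passed and that the naming rule covers, 41, 40, 20 and 24 still passed in these fits. KO and locus deletion shared 354 genes higher and 313 lower than wild type, where independent lists would share 29.21 and 33.8, and 32 genes changed in opposite directions (571, 529 and 52 with a replicate block). The covariance of log2 fold changes was 0.31 against 0.12 in simulations, and the correlation 0.567 against 0.5. The simulations shared 0.05 and 0.15 genes on average. Part of the excess may come from the 2 shared wild-type libraries, not split as each part would hold 1. Chromosome 8 may add to it, with 106 (KO) and 209 (locus deletion) genes lower.

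Set directly against each other, KO and locus deletion ESCs differed in the actin genes beyond Actb itself, with Actg1, Acta2 and Acta1 higher in KO. H19, Krt18, a keratin, and Zscan4d, a gene of the transient state that resembles the early embryo, were also higher in KO. Dppa3, a germline and naive pluripotency gene, and Pof1b, a protein that binds actin, were lower in KO. Some cholesterol synthesis genes, such as Cyp51, were higher in KO than in locus deletion cells.

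Actb was 3.30 higher in KO on the log2 scale (adjusted p = 4.5e-06). Actg1 was 0.72 higher (SE 0.122, adjusted p = 0.0153), Acta2 3.71 higher (SE 0.46, adjusted p = 0.00468) and Acta1 3.43 higher (29.5 ± 2.12 against 2 ± 1.41, SE 0.602, adjusted p = 0.0173), while Actc1 (1.32, adjusted p = 0.319) and Actg2 (1.69, adjusted p = 0.363) did not pass. The actin list had 4 genes that were higher and 0 lower, also adjusted over the list alone (camera, adjusted p = 2.92e-07; adjusted p = 0.389 with an estimated correlation). Actb is 1 of these 4. Its locus is missing in the other group, so its call and part of the list result follow from the design. Each of the 3 calls besides Actb was lost when any 1 library was left out (adjusted p = 0.11 to 0.232 for Actg1, 0.122 to 0.216 for Acta2 and 0.118 to 0.269 for Acta1), and those of Actg1 and Acta1 also in a fit of only the 4 libraries compared (adjusted p = 0.081 and 0.066). Cholesterol synthesis genes were higher in 8 of 21 cases and lower in 0 (13 and 0 adjusted over the list alone; camera, adjusted p = 8.8e-11; adjusted p = 0.382 with an estimated correlation). Hmgcs1, Cyp51 and Msmo1 were among them. WNT targets were higher in 3 of 15 cases, Myc, Cdx1 and Dkk1, and lower in 0 (5 and 2 under a replicate block and also adjusted over the list alone; camera, adjusted p = 0.0204; adjusted p = 0.522 with an estimated correlation). Of the formative and neuroectoderm list 1 of 15, Dnmt3a, was higher and 4 were lower, among them Otx2, Zic2 and Pax6 (camera, adjusted p = 0.032; adjusted p = 0.547 with an estimated correlation). Of S phase genes 1 of 24 was higher and 0 lower (5 and 0 under a replicate block), of kidney tubule markers 2 of 6 and 0, of glycolysis and low-oxygen genes 5 of 29 and 1 (9 and 2 under the block), and of mesoderm genes 4 of 19 and 1. These 4 lists were called (camera, adjusted p = 0.000234, 0.0274, 0.0446 and 0.0466, the last 0.0631 under the block). With an estimated correlation they had an adjusted p of 0.389, 0.516, 0.693 and 0.659. H19 was at 2458 ± 307 against 16 ± 9.90, Krt18 at 320.5 ± 26.2 against 15 ± 0, Nxf7 at 107.5 ± 26.2 against 7.5 ± 3.54, and Zscan4d, 1 of several near-identical copies, at 137.5 ± 0.707 against 2.5 ± 2.12. Pof1b was at 6 ± 1.41 against 130.5 ± 6.36, Dppa3 at 56.5 ± 17.7 against 728 ± 50.9, Grin1 at 20.5 ± 12.02 against 237.5 ± 13.4 and Rassf4 at 23 ± 15.6 against 144.5 ± 24.7. In limma 590 genes were higher and 535 lower in KO, or 909 and 826 with a replicate block. Without KO library 1 or 2 there were 1 and 2 calls, and without locus deletion library 1 or 2 there were 30 and 21. Of the 33 genes that passed and that the naming rule covers, 1, 2, 5 and 5 still passed in these fits. In KO 110 genes were higher and 116 lower than in both other groups (180 and 206 with a replicate block), where independent lists without a block would give 14.41 and 13.07. These comparisons share the KO libraries (covariance of log2 fold changes 0.182 against 0.12 simulated, correlation 0.375 against 0.502), so part of the excess may come from them.

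Of 91 genes similar in sequence to Actb mRNA, 24 were tested, 5 of them actin genes and 12 pseudogenes. In KO against wild type 3 rose, all of them actin genes, and 1 fell (7, 5 of them actin genes, and 1 with a replicate block; camera over the 7 comparisons of this kind, adjusted p = 0.00393; p = 0.237 with an estimated correlation), and against locus deletion 3 were higher and 0 lower (adjusted p = 0.0111; p = 0.296 with an estimated correlation). The locus deletion set was not called against wild type (adjusted p = 0.472). With the gene family left out, 0 of the 7 sets were called (camera; 1 at an unadjusted p below 0.05). The gene that fell was Ubap1l (11.5 against 35.5, adjusted p = 0.0498), chosen after its values were seen.

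In Actg1 KO MEFs, Actg1 mRNA fell and Actg2, the enteric smooth muscle actin, rose many-fold. Acta2 rose and Acta1 fell. Genes of the fibroblast matrix such as Lum, Dcn and Col1a1 rose, along with most genes tested of inflammation and of the integrated stress response and part of the interferon response. Many genes of mitosis fell, and so did Mga, a repressor that pairs with Max. Hoxc6, a positional homeobox gene, rose from almost no expression.

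Actg1 stood at 1015 ± 15.6 (SD, n = 2) in KO and 5704.5 ± 46.0 (SD, n = 2) in wild-type MEFs (log2 fold change −2.49, SE 0.194, adjusted p = 5.3e-05). Actg2 rose from 81 ± 15.6 to 4854.5 ± 296, 59.9-fold (5.90, SE 0.134, adjusted p = 5.08e-07). Acta2 rose from 16073.5 ± 360 to 27672 ± 1611 (0.78, adjusted p = 8.39e-05) and Acta1 fell from 467.5 ± 40.3 to 126 ± 8.49 (−1.88, adjusted p = 1.39e-05). Actb was at 118252 ± 6420 against 101829 ± 2372 (0.21, adjusted p = 0.06). Chromosome medians set to 0 gave 0.08 (adjusted p = 0.364). Actb passed with library totals made equal or genes over 1 percent left out (0.30) or upper quartile scaling (0.26). It also did with precision weights or only the 4 libraries compared, all at adjusted p 0.00165 to 0.0347. Equal totals moved the median gene from 0.0595 to 0.139, and upper quartile scaling to 0.107. All calls of actin genes held with each library left out. The actin list had 2 genes that rose and 2 that fell (3 and 2 adjusted over the list alone) and was not called (camera, adjusted p = 0.776; adjusted p = 0.907 with an estimated correlation).

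Of the integrated stress response list 24 of 25 rose and 0 fell, also adjusted over the list alone (camera, adjusted p = 7.18e-11; adjusted p = 0.364 with an estimated correlation). The cystine transporter Slc7a11 rose by 3.06 on the log2 scale, Vldlr by 2.20, the mitochondrial folate enzyme Aldh1l2 by 2.18 and Gpt2 by 1.95. Of the inflammatory list 18 of 21 rose and 1 fell (camera, adjusted p = 2.66e-08; adjusted p = 0.382 with an estimated correlation). These included the chemokines Cxcl1 (4.33), Cxcl5 (2.84) and Ccl2 (2.37) and the cytokine Il1a (219.5 ± 21.9 against 3.5 ± 0.707). Fibroblast matrix and stromal markers rose in 26 of 37 cases and fell in 5 (27 and 5 adjusted over the list alone; camera, adjusted p = 3.29e-07; adjusted p = 0.543 with an estimated correlation): Lum rose from 8.5 ± 2.12 to 4531.5 ± 33.2, Dcn, a small proteoglycan of collagen fibrils, from 15.5 ± 2.12 to 7845 ± 272, and Col1a1 and Mmp2 rose by 2.64 and 2.47 on the log2 scale. Basement membrane genes rose in 10 of 16 cases and fell in 3 (11 and 3 adjusted over the list alone; camera, adjusted p = 0.0149; adjusted p = 0.67 with an estimated correlation). Lama4 and Nid2 rose and Lama5 fell. SRF and MRTF targets rose in 21 of 33 cases and fell in 4 (24 and 6 adjusted over the list alone; camera, adjusted p = 0.000846; adjusted p = 0.843 with an estimated correlation). Cnn1 (2.10) and Csrp2 (2.02) led them. Interferon genes rose in 14 of 24 cases and fell in 3 (camera, adjusted p = 0.00262; adjusted p = 0.659 with an estimated correlation): Cxcl10 (3.36), Ccl5 (2.44) and Ddx58 (1.76) rose and Ifit2 fell (−1.21). G2 and M phase genes fell in 15 of 27 cases and rose in 0 (17 and 1 adjusted over the list alone; camera, adjusted p = 1.37e-05; adjusted p = 0.643 with an estimated correlation). They included Kif23, Tpx2, Kif20a and Bub1. S phase genes fell in 12 of 24 cases and rose in 3 (camera, adjusted p = 0.00181; adjusted p = 0.659 with an estimated correlation). Of actin regulators 15 of 31 fell and 6 rose (camera, adjusted p = 0.0389; adjusted p = 0.882 with an estimated correlation). Of ribosomal protein genes 16 of 39 fell and 2 rose (camera, adjusted p = 0.00511; adjusted p = 0.88 with an estimated correlation). The mRNA decay list had 7 genes that rose and 8 that fell of 35 (camera, adjusted p = 0.627) and the COMPASS list 3 and 7 of 17 (camera, adjusted p = 0.483), and neither was called.

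Of 21589 genes, 4455 were higher and 4126 lower, and 2336 and 1225 of them by at least 2-fold. Levels in KO and wild type were 1137.5 ± 21.9 and 0.5 ± 0.707 for Chil1, a chitinase-like secreted protein, 1231 ± 26.9 and 2 ± 1.41 for Hoxc6, 613 ± 12.7 and 1 ± 1.41 for Mgst1, 9935 ± 455 and 28 ± 5.66 for Igfbp5, and 401 ± 24.0 and 1 ± 1.41 for the cadherin Cdh6. Brinp3 was at 484 ± 25.5 against 0 in both wild-type libraries, at least 149-fold higher. Zfp518b was at 0 in both KO libraries against 165.5 ± 6.36, at least 52.3-fold lower. Mga fell from 2144.5 ± 20.5 to 12.5 ± 3.54, Hapln1 from 423 ± 1.41 to 2.5 ± 2.12, Nol4 from 148.5 ± 13.4 to 0.5 ± 0.707, Rgs17 from 362 ± 9.90 to 2.5 ± 0.707, Evx2, a homeobox gene beside the Hoxd cluster, from 140.5 ± 12.02 to 1 ± 0, the basement membrane collagen Col18a1 from 4098.5 ± 357 to 75.5 ± 7.78, and Rftn1 from 182 ± 17.0 to 2.5 ± 0.707. All of these had an adjusted p of at most 3.44e-05. Genes of 5 autosomes shifted down as a whole, with medians of −0.53 (chromosome 2), −0.32 (9), −0.33 (12), −0.85 (16) and −0.33 (19), against −0.29 to 0.24 on the other 14. Without KO library 1 there were 4384 calls, and without KO library 2 there were 4484. All 58 genes that passed and that the naming rule covers still passed with each library left out. The 94 genes similar to Actg1 mRNA, 25 tested, had 3 that rose and 7 that fell and were not called (camera, adjusted p = 0.285; p = 0.183 with an estimated correlation).

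In MEFs without the Actg1 locus, Actg1 mRNA was almost gone and Actg2 did not pass the test. Acta2, already abundant in wild-type MEFs, rose, and Actb rose slightly. Many SRF targets rose, with Lmod1, an actin filament nucleator of smooth muscle, Myl9 and Cnn1 among them. Periostin (Postn) and collagen VI genes fell, as did some interferon genes. Ptprd, a receptor phosphatase, and Fzd3, a WNT receptor, were at 0 in both locus deletion libraries.

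Actg1 stood at 20 ± 7.07 (SD, n = 2) (log2 fold change −8.13, adjusted p = 1.36e-06) and Actg2 at 96 ± 2.83 against 81 ± 15.6 (0.26, SE 0.134, adjusted p = 0.229). Acta2 rose to 54116 ± 2131 (1.75, SE 0.0672, adjusted p = 1.18e-05) and Actb to 135944 ± 2319 (0.42, SE 0.0771, adjusted p = 0.00736), the latter a call lost without either wild-type library (highest adjusted p = 0.0625). Acta1 was at 371 ± 21.2 (−0.33, adjusted p = 0.0683), and it passed in alternatives that included library totals made equal (adjusted p = 0.0494), genes with a mean of at least 50 (0.0353), precision weights (0.0395) and chromosome medians set to 0 (0.025). The actin list had 2 genes that rose and 1 that fell (2 and 2 adjusted over the list alone; camera, adjusted p = 0.743; adjusted p = 0.897 with an estimated correlation).

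SRF and MRTF targets rose in 23 of 33 cases and fell in 3 (26 and 5 adjusted over the list alone; camera, adjusted p = 1.18e-10; adjusted p = 0.547 with an estimated correlation): Lmod1 rose from 57 ± 1.41 to 616 ± 48.1, Myl9 by 1.68 and Cnn1 by 1.25 on the log2 scale, while the immediate early gene Egr1 fell by 1.67. Integrin adhesion genes rose in 15 of 35 cases and fell in 7 (21 and 7 adjusted over the list alone; camera, adjusted p = 0.00379; adjusted p = 0.843 with an estimated correlation). Ptk2 and Svil rose and Tns2 fell. Muscle markers rose in 5 of 12 cases and fell in 0 (camera, adjusted p = 0.028; adjusted p = 0.509 with an estimated correlation), among them Smtn, Synpo2 and Tnnt2. Fibroblast matrix markers fell in 15 of 37 cases and rose in 4 (18 and 5 adjusted over the list alone; camera, adjusted p = 0.00115; adjusted p = 0.659 with an estimated correlation). Postn (−3.88) and Col6a2 (−1.89) fell among them. Interferon genes fell in 10 of 24 cases and rose in 0 (camera, adjusted p = 0.000353; adjusted p = 0.63 with an estimated correlation), including the RNA sensor Ddx58 (−1.35) and B2m (−0.53). Of the integrated stress response list 13 of 25 rose and 2 fell (15 and 2 adjusted over the list alone; camera, adjusted p = 4.62e-07; adjusted p = 0.364 with an estimated correlation), and of the unfolded protein response list of the endoplasmic reticulum 10 of 19 rose and 1 fell (13 and 1 adjusted over the list alone; camera, adjusted p = 0.000131; adjusted p = 0.543 with an estimated correlation), among them the chaperone cofactors Sdf2l1 and Manf. G2 and M phase genes rose in 14 of 27 cases and fell in 1 (17 and 1 adjusted over the list alone; camera, adjusted p = 1.5e-07; adjusted p = 0.547 with an estimated correlation), while S phase genes fell in 12 of 24 cases and rose in 2 (14 and 2 adjusted over the list alone; camera, adjusted p = 0.000475; adjusted p = 0.624 with an estimated correlation). Ribosomal protein genes rose in 16 of 39 cases and fell in 1 (18 and 1 adjusted over the list alone; camera, adjusted p = 6.46e-06; adjusted p = 0.692 with an estimated correlation). Of cholesterol synthesis genes 4 of 21 rose and 0 fell, of formative and neuroectoderm genes 1 of 12 rose and 5 fell, and of neural crest and neuronal markers 0 of 6 rose and 4 fell. These lists were called (camera, adjusted p = 0.00495, 0.0358 and 0.0432). With an estimated correlation they had an adjusted p of 0.746, 0.806 and 0.543.

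In limma 2042 genes were higher and 2713 lower, and 435 and 908 of them by at least 2-fold. Besides Lmod1, those that rose most were Pdk4, a kinase that restrains pyruvate oxidation (427.5 ± 37.5 against 25.5 ± 14.8), Nhsl2 (125.5 ± 12.02 against 9.5 ± 0.707), Tns4 (221.5 ± 16.3 against 20 ± 4.24), Cap2, an actin monomer regulator (122 ± 7.07 against 12.5 ± 4.95), Srpx2 (606.5 ± 43.1 against 66 ± 5.66), Gsta4 (369.5 ± 20.5 against 52.5 ± 3.54) and Mrvi1 (320.5 ± 44.5 against 45.5 ± 2.12). Of genes at 0 in both locus deletion libraries, Ptprd was at least 126-fold lower (412.5 ± 20.5 in wild type), Bicd1 at least 64.97-fold, Fzd3 at least 59.3-fold and Coro2a at least 56.3-fold. Etv1 fell from 351 ± 39.6 to 0.5 ± 0.707, Bmp5 from 302.5 ± 13.4 to 0.5 ± 0.707 and Hapln1 from 423 ± 1.41 to 1.5 ± 0.707. The leading genes in both directions had adjusted p of at most 0.000198. Genes of chromosome 4 had a median of −0.49, against −0.21 to 0.21 on the other 18 autosomes. Without wild-type library 1 or 2 there were 1803 and 1918 calls, and without locus deletion library 1 there were 2949. Of the 68 genes that passed and that the naming rule covers, 61, 56 and 64 still passed in these fits, and 62 without locus deletion library 2. The genes similar to Actg1 mRNA were not called, with 5 that rose and 6 that fell (camera, adjusted p = 0.805; p = 0.801 with an estimated correlation). KO and locus deletion shared 734 genes higher and 981 lower than wild type, against 421.4 and 518.5 for independent lists. Opposite changes (1238 genes) had no such number, so agreement is not shown. The covariance of their log2 fold changes was 0.096 against 0.0828 in simulations, and the correlation 0.0975 against 0.498. The 2 wild-type libraries are shared and may give part of the shared excess.

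Set directly against each other, Actg1 KO MEFs had far more Actg2 than locus deletion MEFs and less Acta2 and Acta1. Matrix genes such as Lum and Col6a2 and the growth factor binding protein Igfbp5 were higher in KO. Many chemokine and interferon genes were higher in KO, and many mitotic, ribosomal and cholesterol synthesis genes were lower. The pluripotency factor Sox2 was expressed in KO and at 0 in locus deletion MEFs.

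Actg1 was 5.64 higher in KO on the log2 scale (adjusted p = 1.15e-06) and Actg2 also 5.64 higher (SE 0.134, adjusted p = 3.11e-07). Acta2 was lower (−0.97, SE 0.0672, adjusted p = 2.19e-05), as was Acta1 (−1.55, SE 0.109, adjusted p = 2.32e-05), and Actb did not pass (−0.20, adjusted p = 0.0665) except with chromosome medians set to 0 (−0.49, adjusted p = 0.00013), precision weights (adjusted p = 0.00199) and upper quartile scaling (adjusted p = 0.0338). The actin list was not called, with 2 higher and 2 lower (2 and 3 adjusted over the list alone; camera, adjusted p = 0.951; adjusted p = 0.98 with an estimated correlation). Fibroblast matrix genes were higher in 29 of 37 cases and lower in 4 (30 and 4 adjusted over the list alone; camera, adjusted p = 3.59e-09; adjusted p = 0.522 with an estimated correlation), with a median log2 fold change of 1.05 and with Col6a2 (3.09), Fbln5 (2.46) and Col6a1 (2.32) among them. Inflammatory genes were higher in 18 of 21 cases and lower in 2 (camera, adjusted p = 4.78e-07; adjusted p = 0.389 with an estimated correlation): Cxcl1 was 4.32, Cxcl5 3.89 and Ccl2 2.63 higher, and Lcn2 at least 89.9-fold higher. Interferon genes were higher in 19 of 24 cases and lower in 2 (camera, adjusted p = 6.04e-05; adjusted p = 0.547 with an estimated correlation). They included Cxcl10 (3.96), Ccl5 (3.40) and Ddx58 (3.11). G2 and M phase genes were lower in 22 of 27 cases and higher in 1 (camera, adjusted p = 8.11e-10; adjusted p = 0.543 with an estimated correlation), and ribosomal protein genes lower in 25 of 39 cases and higher in 1 (26 and 1 adjusted over the list alone; camera, adjusted p = 3.82e-07; adjusted p = 0.659 with an estimated correlation). Cholesterol synthesis genes were lower in 11 of 21 cases and higher in 0 (camera, adjusted p = 0.000738; adjusted p = 0.659 with an estimated correlation). Of the integrated stress response list 15 of 25 were higher and 1 lower (camera, adjusted p = 0.00251; adjusted p = 0.382 with an estimated correlation). Of the unfolded protein response list 3 of 19 were higher and 11 lower (camera, adjusted p = 0.0109; adjusted p = 0.659 with an estimated correlation). Of the pluripotency list 8 of 9 tested genes were higher and 1, Klf2, lower (camera, adjusted p = 0.0191; adjusted p = 0.509 with an estimated correlation), with Sox2 at 1316 ± 14.1 against 0 in both locus deletion libraries, at least 400-fold higher, and with a list median of 2.33, or 1.61 with genes at 0 in a group set to their bounds.

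Igfbp5 was at 9935 ± 455 in KO against 0 in both locus deletion libraries, at least 3023-fold higher, and Ptprd at 1373 ± 33.9, at least 418-fold higher. Lum was at 4531.5 ± 33.2 against 0.5 ± 0.707. Zfp518b was at least 156-fold lower in KO (0 against 495 ± 19.8) and Akip1 at least 42.5-fold lower (0 against 134.5 ± 24.7). Mga was at 12.5 ± 3.54 against 2583 ± 139 and Nol4 at 0.5 ± 0.707 against 136.5 ± 23.3. In limma 5286 genes were higher and 4468 lower, with 5759 and 5778 calls in all without KO library 1 or 2. All 47 genes that passed and that the naming rule covers still passed with each library left out. In KO 3311 genes were higher and 3030 lower than in both other groups, where independent lists would give 1091 and 853.9 (covariance of log2 fold changes 1.36 against 0.0831 simulated, correlation 0.811 against 0.5). The KO libraries are shared by these comparisons, so part of the excess may come from them. The genes similar to Actg1 mRNA were not called (camera, adjusted p = 0.303; p = 0.226 with an estimated correlation).

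**Figure D2:**
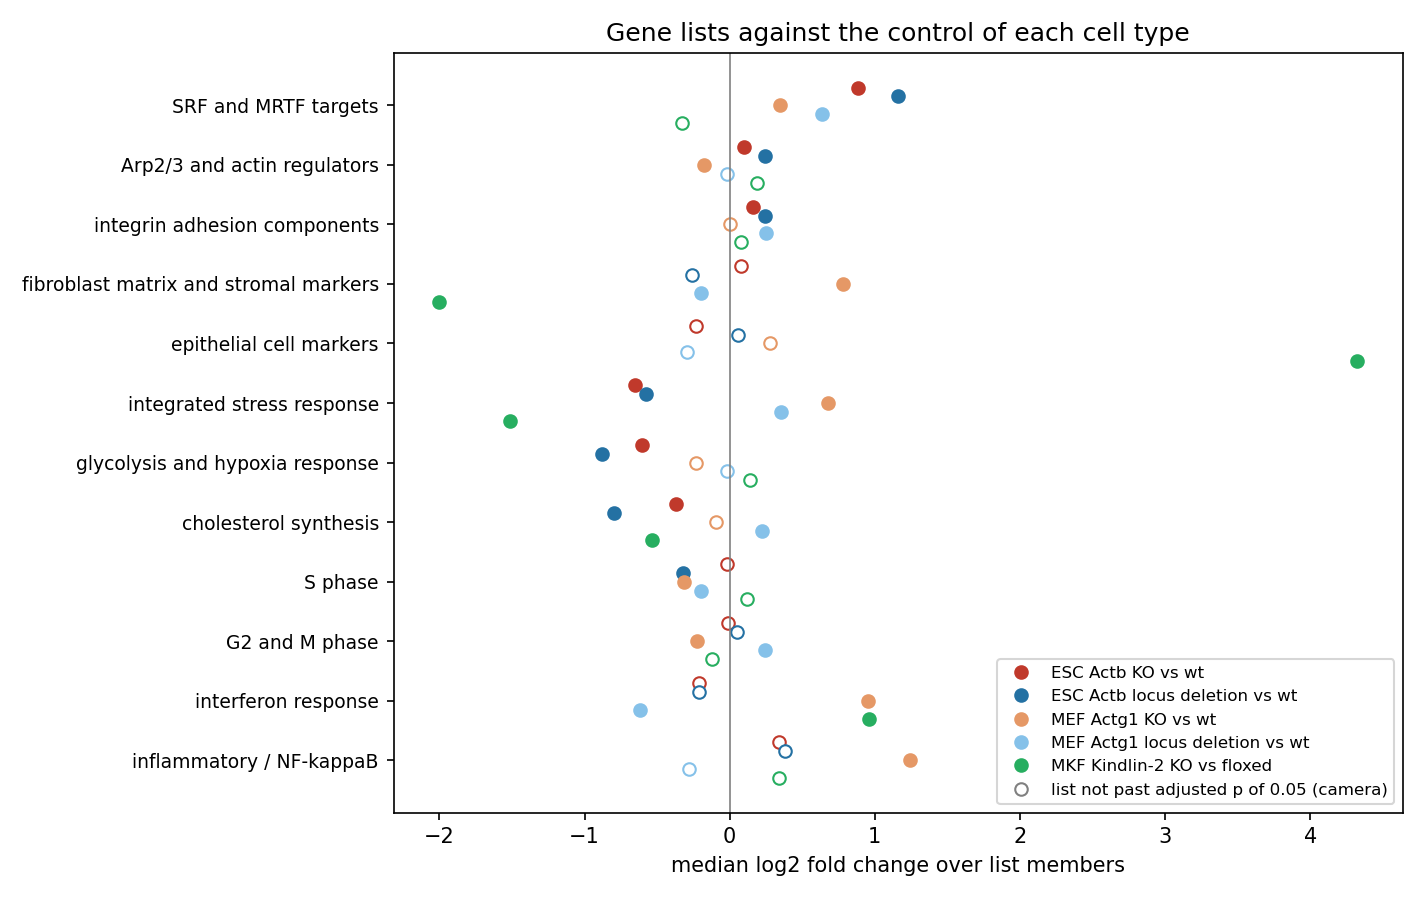
Median log2 fold change of 12 gene lists (horizontal axis) in the 5 comparisons against control; filled points passed camera at an adjusted p below 0.05 with the preset correlation, and open points did not. SRF and MRTF targets stand above 0 in both ESC and both MEF mutants, and epithelial markers in the MKF KO have the median of 4.32.

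In Kindlin-2 KO MKFs, Fermt2 mRNA was lowered and Fermt1, the gene of kindlin-1, which is typical of epithelia, was detected where the floxed cells had none. Most epithelial markers rose with it, among them the keratins Krt7 and Krt18, the tight junction gene Ocln and the splicing regulator Esrp1. The keratin Krt19 rose as well. Fibroblast genes such as the collagen VI chains and Mmp2 fell. Targets of p53 such as the cell cycle inhibitor Cdkn1a rose, and most genes of the integrated stress response and of cholesterol synthesis fell. The Y-linked genes Ddx3y, Eif2s3y and Uty, and the imprinted gene Peg3, were at 0 in both KO libraries.

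Fermt2 stood at 1245.5 ± 7.78 (SD, n = 2) in KO and 3110 ± 45.3 (SD, n = 2) in floxed cells (log2 fold change −1.32, SE 0.0375, adjusted p = 6.14e-05). Fermt1 was at 265 ± 24.0 against 0 in both floxed libraries, at least 83.1-fold higher (adjusted p = 6.78e-05). Fermt3, the kindlin of blood cells, was at 15.5 ± 0.707 against 15 ± 7.07 (0.12, adjusted p = 0.821). The talin genes Tln1 and Tln2 were at 7789.5 ± 326 against 7216 ± 84.9 (0.11, adjusted p = 0.088) and 421 ± 22.6 against 696 ± 5.66 (−0.72, adjusted p = 0.000847). Tln1 passed with library totals made equal (0.14, adjusted p = 0.0388) and upper quartile scaling (0.13, adjusted p = 0.0371), and turned to −0.09 with chromosome medians set to 0 (adjusted p = 0.164), and the call of Tln2 was lost without either floxed library (highest adjusted p = 0.0652). The kindlin and talin list had 1 gene that rose and 2 that fell, also adjusted over the list alone, and was not called (camera, adjusted p = 0.871; adjusted p = 0.94 with an estimated correlation). No group without the Fermt2 locus was part of the design.

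Epithelial markers rose in 18 of 20 cases and fell in 0 (camera, adjusted p = 4.51e-10; adjusted p = 0.364 with an estimated correlation), with a median log2 fold change of 4.32, or 4.02 with genes at 0 in a group set to their bounds. Krt7 was at 3595.5 ± 89.8 against 0 in both floxed libraries, at least 1128-fold higher. Krt18 stood at 13556 against 2013.5, Ocln at 1718 against 11 and the protease St14 at 989 against 4, with log2 fold changes of 2.75, 7.17 and 7.63. Fermt1 was thus higher in the same libraries as the epithelial markers, and 2 of the 20 on the list, Krt7 and Esrp1, had a larger log2 fold change. Fibroblast matrix and stromal markers fell in 19 of 27 cases and rose in 6 (camera, adjusted p = 0.000388; adjusted p = 0.424 with an estimated correlation). Col6a2 stood at −5.15, Col6a1 at −5.14, Loxl2 at −5.01 and Sparc at −1.65. Kidney tubule markers had 3 genes that rose and 3 that fell of 8 and were not called (camera, adjusted p = 0.927). Targets of p53 rose in 17 of 23 cases and fell in 2 (camera, adjusted p = 2.15e-06; adjusted p = 0.382 with an estimated correlation). They included Cdkn1a, Ccng1 (1.72), Plk2 (1.66) and Mdm2 (1.22). The integrated stress response list had 20 genes that fell and 2 that rose of 26 (21 and 3 adjusted over the list alone; camera, adjusted p = 7.83e-08; adjusted p = 0.509 with an estimated correlation). Aldh1l2 stood at −5.57, Vldlr at −2.29, Gpt2 at −2.27 and asparagine synthetase Asns at −1.92. Cholesterol synthesis genes fell in 18 of 21 cases and rose in 1 (19 and 1 adjusted over the list alone; camera, adjusted p = 8.27e-06; adjusted p = 0.509 with an estimated correlation). Interferon genes rose in 11 of 27 cases and fell in 2 (camera, adjusted p = 0.0358; adjusted p = 0.543 with an estimated correlation): Cxcl10 rose (1.15) while B2m (−1.18) and Irf1 (−1.03) fell. The pluripotency list had 4 of 5 that rose and 1 that fell, and the formative and neuroectoderm list 6 of 10 that fell and 0 that rose (camera, adjusted p = 0.0444 and 0.0204; adjusted p = 0.547 for both with an estimated correlation). The mRNA decay list had 11 genes that rose and 8 that fell of 35 and was not called (camera, adjusted p = 0.627).

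Of 18288 genes, 4446 were higher and 4552 lower, and 1811 and 1668 of them by at least 2-fold. Levels in KO and floxed cells were 3675.5 ± 193 and 2.5 ± 3.54 for Mal, a protein of apical membrane transport, 1130.5 ± 54.4 and 0.5 ± 0.707 for Krt19, 1123 ± 12.7 and 0.5 ± 0.707 for Esrp1, and 1123.5 ± 6.36 and 2 ± 1.41 for Gas7. At 0 in both floxed libraries were Hoxd10 (591 ± 69.3 in KO, at least 185-fold higher), Ppp2r2c (531.5 ± 2.12, at least 167-fold) and Wfdc2 (471 ± 26.9, at least 148-fold). At 0 in both KO libraries were Peg3 (3545.5 ± 41.7 in floxed cells, at least 1188-fold lower), Ddx3y (1557 ± 49.5, at least 522-fold), Eif2s3y (1410.5 ± 95.5, at least 473-fold) and Uty (1057.5 ± 37.5, at least 354-fold). Lrrk2 fell from 1281 ± 48.1 to 0.5 ± 0.707, Mmp2 from 820 ± 4.24 to 0.5 ± 0.707 and Dkk3 from 1382 ± 15.6 to 2 ± 1.41. These genes had adjusted p of at most 0.000708. Genes of chromosomes 12 and 16 shifted up (medians 0.69 and 0.35) and those of 9, 10 and 14 down (−0.46, −0.38 and −0.32), against −0.30 to 0.26 on the other 14 autosomes. Genes of chromosome X shifted down as well, with a median of −0.43 over 312 genes. Left out one at a time, KO libraries 1 and 2 gave 3834 and 3662 calls, and floxed libraries 1 and 2 gave 2112 and 2125. Of the 50 genes that passed and that the naming rule covers, 46, 46, 42 and 42 still passed in these fits. Genes similar to any Fermt2 transcript were 3317 tested genes, nearly all of them through transcripts not classed as protein-coding, and were not called (camera, adjusted p = 0.558). The coding transcripts matched only Fermt1 and Fermt3.

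**Figure D3:**
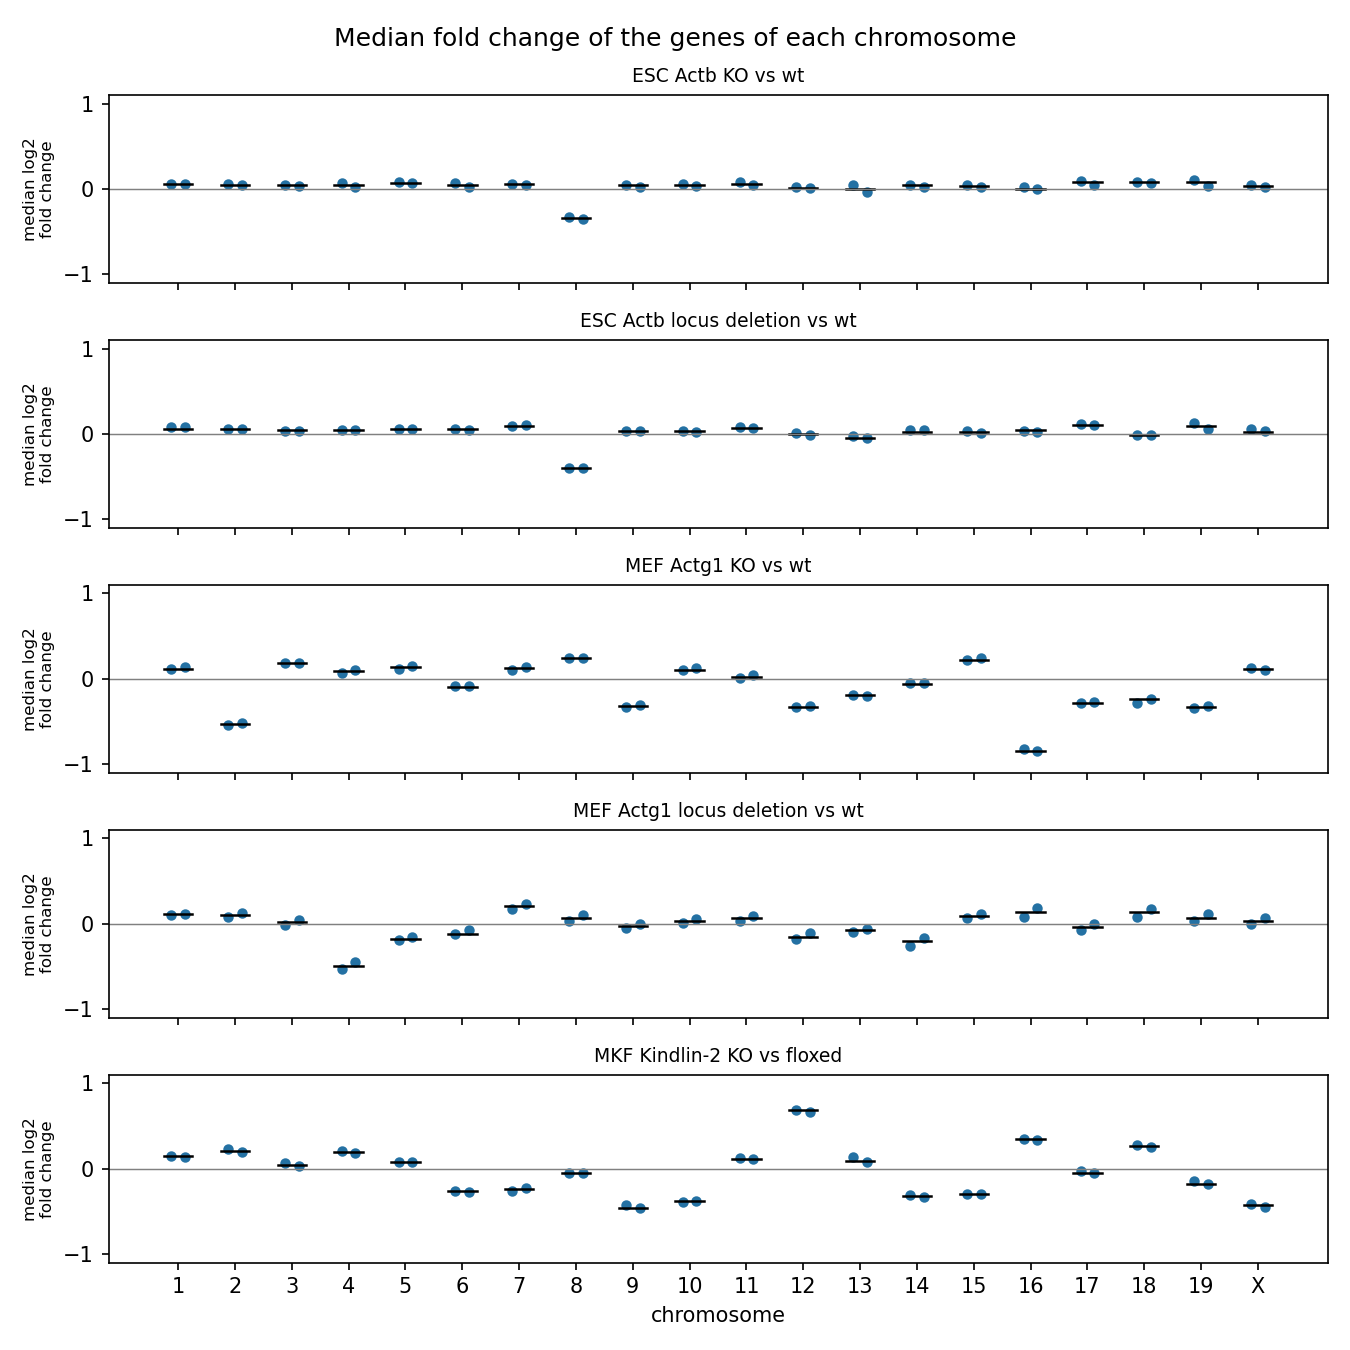
Median log2 fold change of genes per chromosome in the 5 comparisons against control; the line is the group and the 2 points are the mutant libraries. Among the chromosomes that stand apart are 8 in both ESC mutants (−0.35 and −0.40) and 4 in Actg1 locus deletion MEFs (−0.49). Others are 2 and 16 in Actg1 KO MEFs (−0.53 and −0.85) and 9 and 12 in Kindlin-2 KO MKFs (−0.46 and 0.69).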

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

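In this part, the tests on a few strongly changed genes per chromosome and with chromosome medians set to 0 were chosen after the results were seen. The results below stand out because KO and locus deletion cells of a gene differed in a direct test (n = 2 libraries per group).

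In Actb mutant ESCs the KO had more mRNA of other actins than the locus deletion. Actg1 was higher in KO by 0.7184 on the log2 scale, Acta2 by 3.714 and Acta1 by 3.429 (29.5 ± 2.12 against 2 ± 1.41), with both KO libraries above both locus deletion libraries in each case. In MEFs, Actg2 was higher in Actg1 KO than in locus deletion cells by 5.644, while Acta2 (−0.9683) and Acta1 (−1.551) were lower in KO. As groups of genes in MEFs, fibroblast matrix and stromal markers had a median difference of 1.052, interferon genes of 1.845 (1.73 with genes at 0 set to their bounds), G2 and M phase genes of −0.6613 and cytosolic ribosomal protein genes of −0.3473. These 4 list differences passed camera with the preset correlation and none did with an estimated one (adjusted p = 0.522, 0.547, 0.543 and 0.659).

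With chromosome medians set to 0, Actg2 was at 5.625 (MEFs) and Actg1 at 0.7384 (ESCs), while the Acta2 difference in MEFs shrank from −0.9683 to −0.5777. The ESC differences in Actg1, Acta2 and Acta1 lost their calls when any 1 library was left out, with Actg1 between 0.6008 and 0.8359, and the 3 MEF actin differences kept theirs. The MEF lines differed in 9754 genes and in whole chromosomes, so actin genes are a small part of this. The labels do not say how many lines stand behind a genotype. A response to mutant mRNA, which locus deletion is meant to prevent (6.68 percent of Actb mRNA remained), and other line differences were not set against each other. Reads shared among actin genes were not tested here either.

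The first pattern weighed is that genes of single chromosomes shifted together in the mutant lines: chromosome 8 in both ESC mutants, 5 chromosomes in Actg1 KO MEFs, chromosome 4 in Actg1 locus deletion MEFs, and 5 autosomes and chromosome X (median −0.43) in Kindlin-2 KO MKFs. A few strongly changed genes could not move a median of at least 100 genes. Their test (at least 69.7 percent of each autosome's genes on the shift's side) thus cannot decide. A gain or loss of copies of the chromosome, or of a large part of it, would shift genes along its length, and 95.3 percent of the 20 Mb windows of the shifted autosomes were shifted the same way by over 0.5 of the chromosome's median, which is consistent with it. Copy number was not measured, and a difference between the lines present before the gene was disrupted stays open as well. Since both ESC mutants differ from wild type on chromosome 8, the wild-type line may be the one that differs.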

How the results depend on the processing

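The pseudocounts, precision weights, chromosome medians set to 0 and the search with coding transcripts alone were tests chosen after the results were seen; the others were planned. That the numbers pair the ESC libraries was decided after the fits had been compared. Where no cause is named, the cause was not tested. A count test with DESeq2 and TMM scaling with edgeR were not run, because the values are rounded after scaling and are not counts.

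Stricter thresholds call fewer genes by construction. At an adjusted p below 0.01 the numbers were 291 (ESC KO against wild type), 919 (ESC locus deletion), 330 (ESC KO against locus deletion), 2523 (MEF locus deletion) and 5836 (MKF). With an absolute log2 fold change of at least 1 they were 515, 1168, 611, 3561 (MEF KO against wild type), 1343, 4418 (MEF KO against locus deletion) and 3479. Actg1 in ESCs then no longer passed in KO against wild type (0.9798), nor in KO against locus deletion under both thresholds (0.7184). Genes higher and lower in KO than in both other groups were 55 and 39 (ESC) and 1798 and 766 (MEF) at that fold change. Fits of only the 4 libraries compared, which have fewer degrees of freedom, gave 272, 876 and 214 genes in the ESC comparisons and 2986 for MEF locus deletion, and Actg1 in ESC KO against locus deletion (0.7184) had an adjusted p of 0.081.

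Leaving out each library in turn gave 0 to 18 genes (ESC KO against wild type, limma; 2898 at an unadjusted p below 0.05 where it was 0), 58 to 370 (ESC locus deletion), 1 to 30 (ESC KO against locus deletion), 4384 to 5879 (MEF KO), 1803 to 3321 (MEF locus deletion), 5759 to 8205 (MEF KO against locus deletion) and 2112 to 3834 (MKF). The lone library is assumed to vary like the other groups. Actg1 in ESCs ranged from 0.8789 to 1.081 (KO against wild type) and from 0.6008 to 0.8359 (KO against locus deletion), and passed in none of these fits. Actg2 in MEF KO (5.705 to 6.094 against wild type, 5.582 to 5.707 against locus deletion) and Fermt1 in MKFs (7.96 to 8.145) passed in all. Directions turned for genes that had not passed: without wild-type library 2, Fcer1g in ESC KO was −0.2427 (range to 1.565) and Fermt1 in ESC locus deletion −0.02945 (to 1.292), and without floxed library 2, Fermt3 in MKFs was −0.3486 (to 0.5843).

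With a replicate block, the ESC comparisons gave 1850 (KO against wild type), 3727 and 1735 (KO against locus deletion) genes, and 180 and 206 genes were higher and lower in KO than in both others. Of the genes that the naming rule covers, Actc1, Actg2, Kmt2c, Kmt2a, mt-Nd4, mt-Nd6 and Foxd3 gained a call in KO against wild type, Hist1h2ab and Hist1h3d in locus deletion, and Ccne2, Ccne1, Lef1 and Slc12a1 in KO against locus deletion. The list of replication-dependent histones gained one (KO against wild type, adjusted p = 0.0486) and that of mesoderm lost one (KO against locus deletion, adjusted p = 0.0631). The block changed no other call of these genes and lists in ESCs: Actg1 in locus deletion (0.2614) had an adjusted p of 0.0736. In MEFs (correlations −0.302, −0.211 and 0.214) and MKFs (−0.095) libraries share only a number, and the block gave 8159, 4253 and 9421 genes in MEFs and 7496 in MKFs.

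With an estimated correlation 0 of the list tests passed (camera; 26 at an unadjusted p below 0.05), and fry passed 125, 67 of them shared with the 74. Similar genes outside the family gave 0 sets (camera; 1 at an unadjusted p below 0.05), and the MEF locus deletion set turned to −0.01449. With chromosome medians set to 0, Tln1 in MKFs turned to −0.08715. In the remaining alternatives, other scalings, filters, pseudocounts and weights, the number of genes changed stayed within 1.5 times its value in every comparison, and Actg1 in ESCs, Actg2 in MEFs and Fermt1 in MKFs stayed on the same side of the threshold. Depth limits genes with a few reads: a value of 0 in a library allows up to 3 reads. The simulated calls, at gene levels not given here, do not measure this.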

Other observations

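In this part, the tests on floxed cells, on feeder cells by abundant markers, on Actg1 reads and on trophoblast genes, and the look at Hox clusters and at the genes named in the first 2 paragraphs, were chosen after the results were seen, and the rule for the verdict on intact cells was tightened after its value was seen.

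Hox genes, which keep the position of a cell along the body axis, rose as whole clusters in 3 cases, Hoxb and Hoxc in Actg1 KO MEFs and Hoxd in Kindlin-2 KO MKFs; they were looked at after Hoxc6 and Hoxd10 had come up. In Actg1 KO MEFs all 9 tested genes of the Hoxc cluster and all 7 of the Hoxb cluster rose against wild type, with summed values of 1896 ± 26.9 against 4 ± 2.83 and 602 ± 29.7 against 5 ± 2.83 (SD, n = 2). Locus deletion MEFs had summed values of 0.5 ± 0.707 for either cluster. Of the Hoxd cluster 3 genes rose and 1 fell of 6 in KO MEFs, while the summed value was lower than in wild type (1032 ± 6.36 against 2440 ± 89.8), and of the Hoxa cluster 1 rose and 4 fell of 11 (2094 ± 7.07 against 3450 ± 140). In Kindlin-2 KO MKFs all 7 tested Hoxd genes rose (1650 ± 40.3 against 1 ± 0), among them Hoxd8 (736 ± 24.0 against 1 ± 0), while 6 of 8 Hoxc genes fell (989 ± 28.3 against 2162 ± 33.9). Of the Hoxa cluster 2 rose and 4 fell of 9, and of the Hoxb cluster 4 rose and 1 fell of 9. In locus deletion MEFs against wild type 3 of 11 Hoxa, 1 of 7 Hoxb, 1 of 9 Hoxc and 2 of 6 Hoxd genes fell and 0 rose. In ESCs 0 of 26 Hox genes changed in KO (1 with a replicate block) and 1 in locus deletion.

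Some genes known from placenta or imprinting, picked for this, stood higher in Actb KO ESCs than in the other ESC groups, and no list of imprinted genes was tested. Other imprinted genes did not: Dio3 was lower in KO than in locus deletion (470.5 ± 3.54 against 873.5 ± 153), and Peg3 was at 5794 against 5662.5. Peg10, an imprinted gene needed for the placenta, was at 8112.5 ± 694 in KO, 1362.5 ± 124 in locus deletion and 1232.5 ± 153 in wild type. Igf2, the imprinted neighbour of H19, was at 109 ± 25.5, 7.5 ± 0.707 and 28.5 ± 14.8 in the same order, the keratin Krt8 at 315 ± 41.01, 25 ± 1.41 and 98.5 ± 9.19, and the trophoblast regulator Gata2 at 197.5 ± 3.54, 43.5 ± 9.19 and 60 ± 2.83. A list of 30 trophoblast genes, written after the genes that stood higher had been seen, did not pass: of 20 tested in ESC KO against wild type, 1, Peg3, rose and 2 fell (2 and 2 with a replicate block; camera, p = 0.589; p = 0.644 with an estimated correlation). Against locus deletion 2 were higher and 3 lower.

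The next pattern is that Fermt1 and epithelial genes were higher in Kindlin-2 KO MKFs, with 40 percent of Fermt2 mRNA remaining. Floxed cells left in the KO culture are argued against as the source of that Fermt2 mRNA, because 45 of 5244 abundant genes of the floxed line, chromosome Y left out, stood in KO below 0.25 of Fermt2's share. The KO line may differ in epithelial identity as a whole: a further list of epithelial genes, whose values had not been looked at, had a median log2 fold change of 1.65 (1.54 with genes at 0 set to their bounds), and 18 of 24 rose while 0 fell (limma). Fermt1 could thus be high as part of that identity, and 15 genes rose more than Fermt1. A response to mutant mRNA could not be told from it, as no line without the Fermt2 locus was part of the design.

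The last pattern is that 6.68 percent of Actb mRNA remained in ESCs without the Actb locus. Fibroblast feeder cells are argued against: a share of 3.1 percent of the mRNA would be needed, and 4 of 9 abundant fibroblast markers (Bgn, Col12a1, Col1a1 and Col6a3) stood below 0.05 of the level this share would give, while Fn1, Sparc and Vim, which ESCs express too, stood at or above it. A median over 17 markers, set before, had been 0.232 of that level and lay between its bounds of 0.1 and 0.5. Reads of Actg1 counted for Actb stay open: they would have to come to 38.5 percent of the Actg1 level, and only the reverse was measured, Actb reads counted for Actg1, at most 0.0148 percent of the Actb level in MEFs without the Actg1 locus. Cells with an intact locus left in the culture may be the source: 0 of 4819 other abundant genes stood below 0.25 of Actb's remaining share, which met what had been set beforehand for such cells (at most 1), but this was so in Actb KO ESCs as well, so the test cannot decide.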
